A study of Homo sapiens with 18 samples.

How the data were processed

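QGP-1 is an established human cell line from a pancreatic islet carcinoma. The study treated it with butyrate, a short-chain fatty acid made by gut bacteria that is also an inhibitor of histone deacetylases. Per the labels, cells were kept for 24 h in plain medium (control) or in medium with 5 mM butyrate, with 3 replicates in each group. Cells were fixed in 1% formaldehyde for 10 min, and chromatin was cut with MNase and sonicated. ChIP with exogenous reference chromatin (ChIP-Rx) was then done for acetylated lysine 27 (H3K27ac) and lysine 9 (H3K9ac) of histone H3. The H3K27ac antibody was commercial and the H3K9ac antibody was made in-house, per the labels' protocols. There were 12 ChIP libraries, and the 6 input libraries of the series were not analysed here.

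The deposited files were 12 peak lists, one for each ChIP library, so peaks were called per library and not on pooled replicates. Each list had 5 columns: chromosome, start, end, peak name and a score. The submitters' processing notes name BWA, MACS2 and the genome builds hg38 and dm6, with no versions and no roles (not given in the sources used here). The deposited score of each peak is the authors' own value on a scale not given in the sources used here, and the lowest score in every list was just above 2. Positions and scores are the authors' values, and scores were used to rank peaks within lists. The stricter-score alternative alone applied the same score to all lists of a mark. The lists hold no read counts, so the sequencing depth of each library is unknown. No interval that needs the depth was computed, and no statement about total acetylation can be made. Whether the reference chromatin was used to scale the libraries before peak calling is not given in the sources used here. A list shows where a caller found enrichment over that library's own background, so a general rise in background acetylation can shorten or remove peaks.

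Peaks on chromosomes 1 to 22 and X were kept, which left out at most 1 peak per list. The main measure was the covered length, the base pairs of a window that lie inside peaks. Gene names and spans came from the RefSeq annotation of GRCh38.p14, whose coordinates are those of hg38, with 59084 genes on these chromosomes. The annotation used here gives the lower and upper end of each gene but no strand and no transcripts. The planned 5′ end was therefore replaced. For each gene the end with the larger mean covered length within 2500 bp over all 12 libraries was used. The choice uses no treatment labels, but the butyrate libraries enter the mean. An end can thus be chosen because it gains coverage with butyrate, or because of its control coverage. Of 51 genes whose strand was known beforehand, 49 had coverage, and for 46 of these the end chosen was the 5′ end. The exceptions were SST, HDAC1 and E2F1. This share does not hold for the named gains. By known strands of the genes named among the gains and the largest losses, looked up after the values were seen, the end used was the 3′ end for 23 of 28 genes higher with butyrate and for 5 of 16 among the largest losses. Windows are called gene-end windows for this reason, are 5001 bp long, and can hold the ends of neighbouring genes. Lengths are in base pairs throughout, as mean ± SD of 3 libraries per group. Exons, introns and untranslated regions were not annotated.

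Counts of peaks, covered length, median width, shares of covered length, overlap of the marks and counts of long regions were compared with exact two-sided permutation tests of 3 against 3 libraries. The smallest p these allow is 0.1, so none can pass 0.05. Features were the 1 kb on either side of the chosen gene end, the rest of gene spans, and intergenic sequence. Gene-end windows covered in at least 2 of the 6 libraries of a mark were tested with limma (two-sided, no trend, not robust). P-values were adjusted by the Benjamini-Hochberg method over all windows tested, with a threshold of 0.05. The difference between marks was tested as the mark-by-treatment interaction over the 12 libraries, taken as independent. The 21 gene lists were fixed before the data were examined and tested with camera at an inter-gene correlation of 0.01, where at least 3 members were tested. Camera asks whether a list's windows differ from all other windows. It was run on differences in base pairs, so a list with longer control lengths can fall further. Sites were merged regions over the 6 lists of a mark, with an overlap of 1 bp, called in all 3 libraries of one treatment and in none of the other. Long regions were peaks stitched within 12 kb that reached 20 kb. Genes were named by a rule fixed before the data were examined. It took, for each mark, the 10 largest increases and 10 largest decreases among protein-coding genes past the test with separated groups. It added up to 4 passing members of each list by smallest p, 12 genes chosen in advance, and the genes in the 5 longest regions called in one treatment only. Added after the values were seen were the list members that were higher with butyrate, and the 3 coding genes with the clearest opposite directions of the marks. These are pointed out where they appear. Some genes and a region that the rule names are not reported here, and the counts over named genes leave these genes out.

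Nothing in the labels says that the 3 replicates were grown as separate cultures, so p-values measure the spread between these samples. Replicate numbers are shared by control and butyrate and were not taken as pairs there. Correlations were taken after subtracting the group mean of each window. Libraries of both marks with the same treatment and number then correlated at 0.19 to 0.32. Every pair was over 0.1, so they were taken as coming from the same chromatin. The test of the difference between marks does not use this pairing. With it as a block, 1612 windows favoured H3K27ac and 579 favoured H3K9ac, in place of 1343 and 496. File names and track lines give a sequencing lane. For each mark the 3 butyrate libraries and control replicate 1 were in lane 4, and the 2 other control libraries were in lane 5. Lane and treatment therefore overlap in part, and with lane as a term the butyrate effect is estimated against control replicate 1 alone.

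The alternatives were a stricter score, equal numbers of peaks, scaling, other windows, filters and overlaps, leaving out each replicate, and the replicate number as a block. Chosen after the data were examined were the whole gene span, protein-coding genes only, and lane as a term. The limma step was tested on simulated covered lengths with 200 changed windows. Simulated windows varied independently, and far more windows were called in the data, so the rates below do not describe the real calls. On the 20381 windows of H3K27ac it called 43 of 100 windows changed by 1500 bp and 9 of 100 changed by 750 bp, with 0 false calls. On the 20276 windows of H3K9ac it called 41 and 4 of 100, with 1 false call. For the difference between marks, on 20276 simulated windows, it called 68 of 200 windows changed by 1500 bp, with 3 false calls. Site and interval steps returned every planted site. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.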

Results

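Acetylation of histone H3 was mapped in QGP-1, an endocrine tumour cell line, in a series on enterochromaffin cells, the serotonin-releasing endocrine cells of the gut, and microbial metabolites. The comparison asks how butyrate changes the acetylated regions. The 12 peak lists fall into 4 groups of 3 libraries: H3K27ac and H3K9ac, each in control cells and in cells given 5 mM butyrate for 24 h. H3K27ac marks active promoters and enhancers, and H3K9ac lies mostly at active promoters. The H3K27ac lists held 53430, 50323 and 50836 peaks in control and 92041, 62199 and 101852 peaks with butyrate. The H3K9ac lists held 49126, 44819 and 40784 peaks in control and 53254, 27841 and 54389 with butyrate. Butyrate replicate 2 had the shortest butyrate list for both marks. Read depth is unknown.

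With butyrate, acetylated regions were spread over gene bodies in shorter peaks, and a smaller part of them lay at gene ends. Sequence within 1 kb of a gene end made up 35.8% ± 0.51 of the H3K27ac covered length in control and 19.2% ± 0.40 with butyrate (SD, n = 3 per group). Gene bodies held 48.2% ± 0.51 in control and 65.7% ± 0.85 with butyrate, and intergenic sequence 15.9% ± 0.03 and 15.1% ± 0.68. For H3K9ac, the gene-end share was 50.2% ± 2.14 in control and 34.3% ± 5.86 with butyrate, and the gene-body share was 41.8% ± 1.54 and 58.7% ± 4.05. The intergenic share of H3K9ac was 7.99% ± 0.77 and 6.92% ± 2.04, with overlapping groups (exact permutation test, p = 0.6). For comparison, gene ends, gene bodies and intergenic sequence take up 3.55%, 52.8% and 43.7% of the annotated span of the chromosomes. The median H3K27ac peak was 512 ± 22.5 bp wide in control and 321 ± 16 bp with butyrate, and the median H3K9ac peak 428 ± 12.5 bp and 304 ± 12.5 bp. Mean peak numbers for H3K27ac were 51529 ± 1666 in control and 85363 ± 20652 with butyrate. Apart from the intergenic H3K9ac share, the groups did not overlap in any of these, with p = 0.1 in the exact two-sided permutation test, the smallest that 3 against 3 libraries can give. Keeping only peaks above a stricter score turned the H3K27ac peak number (6899 ± 1924 with butyrate, 25043 ± 1200 in control) and its median width (1314 ± 104 bp and 1092 ± 54.2 bp). It also turned the intergenic share of H3K27ac. With equal peak numbers the median widths were 527.7 ± 3.51 bp in control and 439.5 ± 54.2 bp with butyrate for H3K27ac, and 739 ± 70.1 bp and 363 ± 39.7 bp for H3K9ac (exact permutation tests, p = 0.1 each). The stricter score was 1 value for all lists of a mark, and scores were lower in the butyrate lists. Their upper quartile was 10.4 to 10.5 with butyrate and 67.3 to 85.0 in control for H3K27ac, and 7.80 to 8.80 and 32.9 to 41.9 for H3K9ac.

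**Figure D1:**
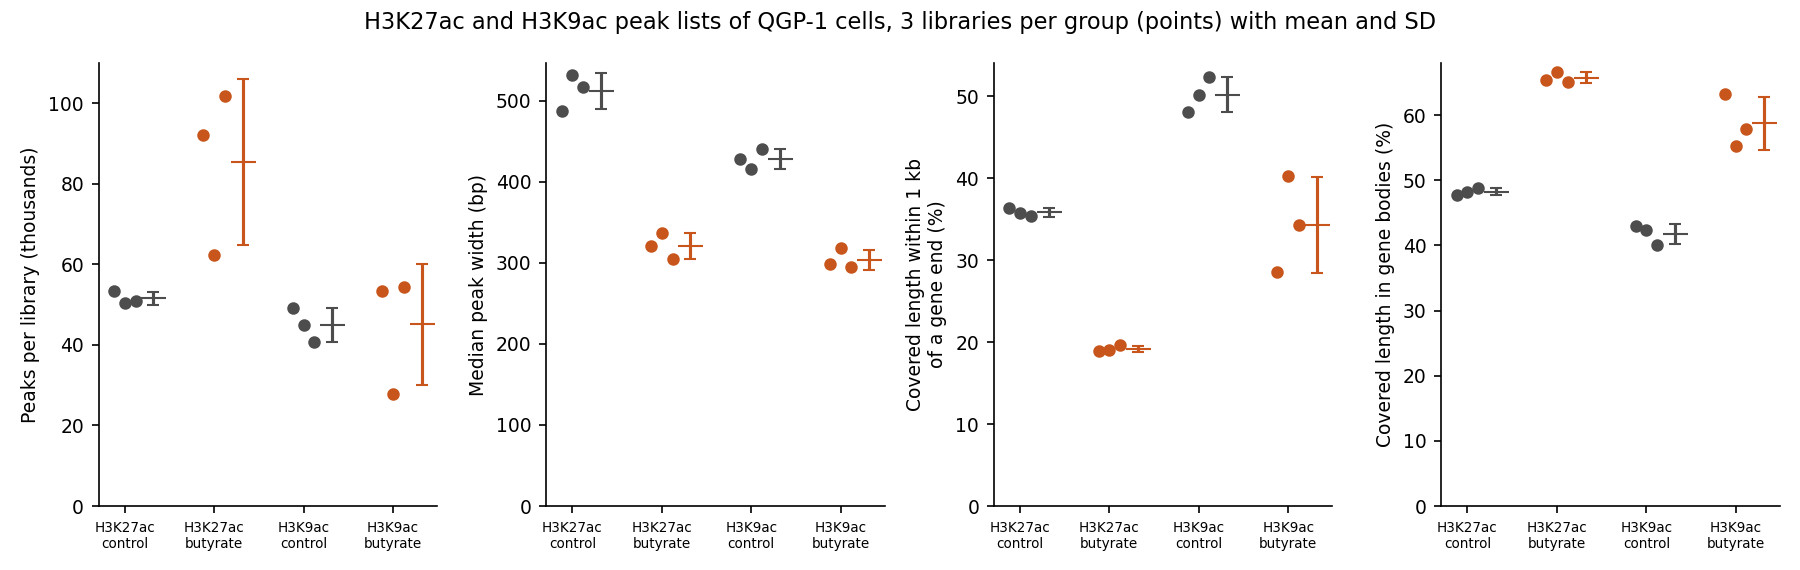
Peak number (in units of 1000), median peak width (bp) and the percent of covered length near gene ends and in gene bodies, for each mark and treatment; points are the 3 libraries, horizontal bars the mean and whiskers the SD. All 3 butyrate libraries lie below all 3 control libraries in gene-end share (19.2% against 35.8% for H3K27ac on average) and above them in gene-body share (65.7% against 48.2%).

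H3K27ac peaks covered 46.5 ± 0.26 Mb in control and 44.9 ± 9.58 Mb with butyrate, with overlapping groups (exact permutation test, p = 1). H3K9ac peaks covered 30.9 ± 3.46 Mb in control and 19.3 ± 5.62 Mb with butyrate (exact permutation test, p = 0.1). With equal peak numbers H3K27ac covered 46.2 ± 0.66 Mb in control and 35.0 ± 3.93 Mb with butyrate, and with a stricter score 37.0 ± 0.54 Mb and 12.1 ± 3.13 Mb (exact permutation tests, p = 0.1 each). Mean H3K9ac peak numbers were 44909 ± 4172 in control and 45161 ± 15010 with butyrate (exact permutation test, p = 1), but butyrate replicates 1 and 3 lay above every control library and replicate 2 below. Without butyrate replicate 2 the butyrate mean was 53820.5, above all controls, and with a stricter score the means were 20619.7 with butyrate and 33951 in control, with no overlap. Control replicate 1, the only control sample of each mark in the lane of the butyrate libraries, covered 46.2 Mb for H3K27ac and 34.5 Mb for H3K9ac. Its gene-end shares were 36.4% and 48.1%. Lane 5 held control libraries only, so it gives no comparison.

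At the ends of genes the covered length fell widely. Of 20381 gene-end windows tested for H3K27ac, 13104 fell and 1254 rose with butyrate, and the median difference was -771 bp. For H3K9ac, 12894 of 20276 windows fell and 296 rose, with a median difference of -813 bp (limma, adjusted p under the threshold in each). Leaving out 1 library gave 897 to 1894 higher windows for H3K27ac and 131 to 726 for H3K9ac. Among protein-coding genes 8966 of 12497 windows fell for H3K27ac and 8923 of 13320 for H3K9ac. Of 18098 windows tested for both marks, 10535 fell for both, where independent lists of these sizes would share 8911. Both marks rose at 123 windows, where independent lists would share 7.26. These lists come from the same cell samples, so part of the excess can come from shared chromatin. When each library was scaled to the mean of windows covered in all libraries, the median differences were -339 bp and -281 bp. The share of calls that were higher then went from 8.73% to 27.9% for H3K27ac and from 2.24% to 22.5% for H3K9ac. Lane as a term left 659 higher and 8890 lower windows for H3K27ac, and 60 higher and 10800 lower for H3K9ac, with the effect then taken against control replicate 1 alone.

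The largest H3K27ac losses were at MYT1L, a neuronal transcription factor (chromosome 2, 1789113 to 2331275, GRCh38), with 0 ± 0 bp with butyrate and 4493 ± 224 bp in control. Values joined by "against" give butyrate first and control last, as mean ± SD of 3 libraries. TMSB4X, which encodes the actin-binding thymosin beta 4, had 337 ± 428 bp against 4685 ± 121 bp. The histone gene H3C4 had 490.3 ± 308 bp against 4757 ± 73.3 bp and the forkhead factor FOXO3 568 ± 313 bp against 4478 ± 178 bp. JARID2, a partner of the Polycomb complex, had 189 ± 182 bp against 3753 ± 225 bp, and the kinesin gene KIF18A had 187 ± 189 bp against 3741 ± 434 bp. The windows of ISCU and SART3 overlap and share peaks, as do those of LETM2 and NSD3. They had 371 ± 236 bp against 4037 ± 217 bp at ISCU, 411 ± 235 bp against 4029 ± 211 bp at SART3, 1375 ± 609 bp against 5001 ± 0 bp at LETM2 and 1419 ± 681 bp against 4966 ± 61.2 bp at NSD3. For H3K9ac the largest losses were at MACC1 (308 ± 533 bp against 4955 ± 39.9 bp), the Notch target HES1 (252 ± 437 bp against 4894 ± 64.9 bp) and IRF2BP2 (140.3 ± 122 bp against 4726 ± 187 bp). BTG1, an antiproliferative gene, had 92.3 ± 132 bp against 4557 ± 416 bp and PTCHD4 had 195 ± 104 bp against 4555 ± 125 bp. FOXO3, LETM2 and NSD3 were among the 10 largest losses for both marks, with H3K9ac lengths of 189 ± 328 bp against 4284 ± 212 bp, 170.3 ± 149 bp against 4446 ± 155 bp and 170.3 ± 149 bp against 4438 ± 146 bp. The 10 also held DLGAP1 (99.3 ± 148 bp against 4251 ± 267 bp). Adjusted p-values ran from 4.64e-05 to 0.000454 for the H3K27ac losses and from 7.52e-05 to 0.000135 for those of H3K9ac.

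The windows with the largest gains often held the ends of 2 genes, and most of the named gains lay at 3′ ends. The choice of end used coverage that includes the butyrate libraries, which can favour ends with gains. By known strands, looked up after the values were seen, the end used was the 3′ end for 23 of 28 named genes that were higher with butyrate, and the 5′ end for 11 of 16 among the largest losses. PLEKHG5, a guanine nucleotide exchange factor (chromosome 1, 6467122 to 6520092), had 4943 ± 99.9 bp with butyrate and 65.7 ± 84.5 bp in control of H3K27ac. Its neighbour TNFRSF25 shares most of that window and had 4462 ± 217 bp against 0 ± 0 bp. MFAP4 (chromosome 17, 19383445 to 19387190), whose window holds an end of the kinase gene MAPK7, had 4829 ± 91.8 bp against 0 ± 0 bp. LAMTOR4, a subunit of the lysosomal Ragulator complex (chromosome 7, 100148918 to 100154203), had 4767 ± 264 bp against 404 ± 130.5 bp. The window lies at the 3′ end of LAMTOR4 and also holds an end of TRAPPC14. SNX22, next to PPIB, had 4905 ± 72 bp against 653 ± 387 bp. HABP2 had 4804 ± 26.8 bp against 734 ± 379 bp, CCDC17 next to NASP 4324 ± 166 bp against 222 ± 221 bp and CAPS next to RANBP3 4154 ± 648 bp against 127 ± 109.9 bp. LOC124900389, next to USP22, had 4413 ± 116 bp against 0 ± 0 bp. PLEKHG5, MFAP4, LAMTOR4 and SNX22 were also among the 10 largest H3K9ac gains, with 2100.3 ± 693 bp against 95.3 ± 165 bp, 2284 ± 597 bp against 225 ± 239 bp, 2881 ± 169 bp against 717 ± 296 bp and 2429 ± 240.0 bp against 753 ± 653 bp. The others were the overlapping windows of BGLAP (3409 ± 1058 bp against 746 ± 720.2 bp) and PAQR6 (3408 ± 1056 bp against 746 ± 720.2 bp), then QRICH2, ESPN, the potassium channel gene KCNN3 and the bile acid receptor gene GPBAR1. They had 2196 ± 1658 bp against 0 ± 0 bp, 1992 ± 519 bp against 0 ± 0 bp, 2320.3 ± 84.1 bp against 367 ± 354 bp and 1821 ± 508 bp against 61.7 ± 107 bp in this order. Adjusted p-values ran from 2.3e-05 to 0.00031 for H3K27ac and from 0.0003 to 0.041 for H3K9ac. The call for QRICH2 was lost under 12 of its 17 alternatives. With a stricter score, the H3K27ac calls of MFAP4 and LOC124900389 and the H3K9ac calls of BGLAP and PAQR6 were lost. Lane as a term ended the H3K9ac calls of BGLAP, PAQR6, QRICH2 and SNX22.

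Genes of serotonin synthesis and handling lost covered length at nearly every window tested. All 10 tested H3K27ac windows of this list fell, and 10 of 11 H3K9ac windows fell, with the same counts when adjusted over the list alone. TPH1, the rate-limiting enzyme of serotonin synthesis in enterochromaffin cells (chromosome 11, 18017555 to 18046269), had 840 ± 344 bp with butyrate and 2268 ± 302 bp in control of H3K27ac (adjusted p = 0.0026). Its H3K9ac length was 349 ± 306 bp against 1792 ± 291 bp (limma, adjusted p = 0.0019). The H3K27ac call of TPH1 was lost over the whole gene span. GCH1 and PTS, enzymes of the cofactor tetrahydrobiopterin, had H3K27ac lengths of 219 ± 33.5 bp against 1448 ± 28.6 bp and 653 ± 366 bp against 2169 ± 108 bp, and the cofactor-recycling gene PCBD1 an H3K9ac length of 542 ± 62.7 bp against 1331 ± 99.8 bp. The amino acid transporter gene SLC7A8 and the serotonin-degrading enzyme gene MAOA fell for both marks, to H3K27ac lengths of 1408 ± 277 bp against 2696 ± 140.0 bp and 645 ± 301 bp against 1865 ± 42.5 bp. Their H3K9ac lengths were 783 ± 363 bp against 2502 ± 42.2 bp and 237 ± 411 bp against 1708 ± 63.8 bp. DDC and SLC18A1, which encode the decarboxylase and a vesicular monoamine transporter, had no covered base in any of the 12 libraries. As a list these genes did not stand apart from all other windows (camera, adjusted p = 0.27 for H3K27ac and 0.28 for H3K9ac).

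Genes of the neuroendocrine granule and of exocytosis fell in 20 of 27 tested H3K27ac windows and in 24 of 27 H3K9ac windows (20 and 25 adjusted over the list alone). CPE, a prohormone-processing enzyme, had 1397 ± 381 bp against 3407 ± 203 bp of H3K27ac and 353 ± 80.3 bp against 2957 ± 263 bp of H3K9ac, and PCSK1 had 1214 ± 164 bp against 3435 ± 149 bp of H3K9ac. RAB3C went from 1635 ± 41.4 bp of H3K27ac in control to no covered base with butyrate, and its H3K9ac length was 0 ± 0 bp against 1829.7 ± 126 bp. SYT4 and SCG3 had H3K27ac lengths of 2338 ± 70.6 bp against 3815 ± 76.7 bp and 185 ± 187 bp against 1838 ± 180.3 bp, and RIMS2 an H3K9ac length of 787 ± 465 bp against 3901 ± 314 bp. CHGA, the granule protein chromogranin A, had 1818 ± 609 bp against 3014 ± 223 bp of H3K27ac and 1236 ± 356 bp against 2350.3 ± 52.3 bp of H3K9ac (adjusted p = 0.016 and 0.0032), and both calls were lost under scaling. The H3K27ac call of CHGA was lost in 6 of 18 alternatives. The list did not pass camera (adjusted p = 0.27 and 0.082).

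Endocrine transcription factors fell in 15 of 17 tested H3K27ac windows and 14 of 17 H3K9ac windows, also when adjusted over the list alone. For H3K9ac the list stood below other windows (camera, adjusted p = 0.041). This was lost in camera with an estimated correlation (adjusted p = 0.61) and with equal peak numbers (adjusted p = 0.27). The list's median H3K9ac control length was 2564 bp, against 1607 bp over all windows, so it had more length to lose. FOXA1, a pioneer factor of endodermal tissues (chromosome 14, 37589552 to 37595249), had 2025 ± 467 bp against 4549 ± 159.7 bp of H3K27ac and 297 ± 145 bp against 3921 ± 90.8 bp of H3K9ac. INSM1, which drives neuroendocrine differentiation, had an H3K9ac length of 0 ± 0 bp against 3087 ± 131 bp, and RFX3 had 782 ± 205 bp against 3453 ± 223 bp. NKX2-2, an islet cell factor, had an H3K27ac length of 58.3 ± 101 bp against 1059 ± 137 bp. NEUROD1 had no covered base in any library. For H3K27ac the list had an adjusted camera p of 0.29.

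Of the gut and islet hormone genes, 5 of 8 tested windows fell for each mark (4 and 5 adjusted over the list alone). Neurotensin (NTS) had 188 ± 17.2 bp against 1488 ± 170.4 bp of H3K27ac and 0 ± 0 bp against 1452 ± 387 bp of H3K9ac. CALCB had 508 ± 177 bp against 1647 ± 149 bp and 0 ± 0 bp against 1441 ± 128 bp. CALCA, the calcitonin gene, had 1171 ± 304 bp against 4637 ± 391 bp of H3K9ac. Its H3K27ac length was 4244 ± 334 bp against 4973 ± 48.5 bp, a call that turned to higher under scaling. Control peaks nearly filled this window, and scaled lengths were not capped at 5001 bp. Scaled values there can exceed what the window holds. UCN3 had an H3K27ac length of 0 ± 0 bp against 279 ± 75.7 bp, a call lost in 9 of 16 alternatives. SST, which encodes somatostatin, had 77 ± 133 bp against 822 ± 234 bp of H3K9ac, and its H3K27ac length of 518 ± 518 bp against 1341 ± 308 bp had overlapping groups (adjusted p = 0.046, lost in 11 of 17 alternatives). The end used for SST is its 3′ end. The list's median windows lay at -504 and -560 bp while camera placed it above other windows, without passing (adjusted p = 0.78 and 0.69).

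Receptors for metabolites and nutrients went both ways. For H3K27ac 3 of 10 tested windows rose and 3 fell (2 and 3 adjusted over the list alone), and for H3K9ac 1 of 6 rose and 4 fell in both counts. GPBAR1, the membrane receptor for bile acids (chromosome 2, 218259496 to 218263861, in a window at its 3′ end that also holds an end of AAMP), rose for both marks. It had 1393 ± 474 bp with butyrate and 0 ± 0 bp in control of H3K27ac (adjusted p = 0.0032). GPR84, a receptor for medium-chain fatty acids, has a window at its 3′ end that also holds an end of COPZ1. It rose for H3K27ac (3491 ± 426 bp against 2408 ± 60.2 bp) and fell for H3K9ac (345 ± 359 bp against 1653 ± 569.6 bp). Its calls were lost with lane as a term. LPAR5, named after its value was seen, had 239 ± 23.4 bp against 0 ± 0 bp of H3K27ac at its 3′ end. The call (limma, adjusted p = 0.047) was lost in 10 of 15 alternatives. AHR, a sensor of tryptophan metabolites, had 1229.7 ± 112 bp against 2117 ± 178 bp of H3K27ac and 634 ± 404 bp against 2000 ± 236 bp of H3K9ac, and both calls were lost under scaling and with 1000 bp windows. GPRC5C had 682 ± 626 bp against 2752 ± 77.7 bp of H3K27ac, and OR51E2, an olfactory receptor that responds to short-chain fatty acids, had 113 ± 196 bp against 1860 ± 318 bp of H3K9ac. FFAR2 and FFAR3, the main receptors of short-chain fatty acids, had no covered base in any library. The list did not pass camera (limma, adjusted p = 0.054 for H3K27ac, pointing up, and 0.69 for H3K9ac). Its median H3K27ac control length was 506 bp, against 1620 bp over all windows.

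Among genes of short-chain fatty acid transport and oxidation, 10 of 14 H3K27ac windows fell and 1 rose, and 9 of 16 H3K9ac windows fell and 1 rose, also when adjusted over the list alone. The window that rose for both marks lay at the 3′ end of SLC16A3, the monocarboxylate transporter MCT4 (chromosome 17, 82217934 to 82240086), and also holds an end of CSNK1D. It had 4260.3 ± 499 bp with butyrate and 630.3 ± 413 bp in control of H3K27ac and 1900.3 ± 821 bp against 339 ± 299 bp of H3K9ac (adjusted p = 0.000375 and 0.015). The H3K9ac value was taken up after it was seen. Its call was lost with lane as a term, without control replicate 2 and without control replicate 3. The oxidation enzymes ACADM and CPT2 had H3K27ac lengths of 516 ± 450.2 bp against 2259 ± 243 bp and 607 ± 155 bp against 1819 ± 115 bp, and ACADM an H3K9ac length of 193 ± 172 bp against 2178 ± 118 bp. HADHA and HADHB have overlapping windows with the same peaks and 479.7 ± 149 bp against 2223 ± 205 bp of H3K9ac each. PDK4 had 229 ± 264 bp against 1441 ± 92.5 bp and 86.3 ± 149.5 bp against 1568 ± 154 bp, and its H3K27ac difference turned over the whole gene span. The list did not pass camera (adjusted p = 0.78 and 0.69).

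Proliferation genes fell in 24 of 30 H3K27ac windows and 28 of 30 H3K9ac windows, in both counts. For H3K9ac the list stood below other windows (camera, adjusted p = 0.048). This was lost in camera with an estimated correlation (adjusted p = 0.90) and with equal peak numbers (adjusted p = 0.13). The list's median H3K9ac control length was 1803 bp, against 1607 bp over all windows. MYC (chromosome 8, 127735434 to 127742951) had 649.7 ± 133 bp against 3139 ± 101 bp of H3K9ac, and its H3K27ac length was 2149.7 ± 756 bp against 3519.7 ± 63.1 bp (adjusted p = 0.017, lost in 7 of 18 alternatives, among them scaling, lane as a term and leaving out any control library). The replication helicase genes MCM4 and MCM5 had 1820 ± 41.8 bp and 1093 ± 20.1 bp of H3K27ac in control and none with butyrate. MCM6 had 59.3 ± 103 bp against 1178 ± 82.9 bp and E2F2 0 ± 0 bp against 1766 ± 312 bp. MCM4, RRM2 and CCND1 had H3K9ac lengths of 0 ± 0 bp against 1809.7 ± 255 bp, 269 ± 466 bp against 3841 ± 104 bp and 249 ± 431 bp against 3705 ± 387 bp. The list's adjusted p for H3K27ac was 0.27.

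Genes known to respond to deacetylase inhibitors fell in 16 of 22 H3K27ac windows and 14 of 25 H3K9ac windows in both counts, and none rose. RHOB had 484 ± 41.3 bp against 2154 ± 85.5 bp and 1143 ± 199 bp against 2410.3 ± 234 bp, and GADD45G 1244 ± 662 bp against 3919 ± 109 bp and 195 ± 169 bp against 3311 ± 403 bp. KLF2 and SYT11 had H3K27ac lengths of 65.7 ± 114 bp against 1312 ± 83.4 bp and 612 ± 256 bp against 3008 ± 464 bp, and CDKN2B and KLF6 H3K9ac lengths of 0 ± 0 bp against 1473 ± 44.2 bp and 2123 ± 249.6 bp against 3641 ± 131 bp. CDKN1A, the cell cycle inhibitor p21, did not pass, with 0 ± 0 bp against 205 ± 30.3 bp and 0 ± 0 bp against 202 ± 24.5 bp (adjusted p = 0.075 and 0.14), but was called lower in 5 of 16 alternatives for H3K27ac and 2 of 16 for H3K9ac. The list did not pass camera (adjusted p = 0.40 and 0.69).

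Among histone deacetylases, sirtuins and their corepressors 16 of 22 windows fell for each mark in both counts. SIRT1 had 57.3 ± 99.3 bp against 1383 ± 144 bp and SIRT3 1182 ± 168 bp against 2490.3 ± 90.2 bp of H3K27ac. The SIRT3 difference turned over the whole gene span. HDAC6 had 873 ± 275 bp against 2771 ± 331 bp of H3K27ac and 182 ± 178 bp against 2076 ± 195 bp of H3K9ac, and RCOR1 1276 ± 378 bp against 3203 ± 199 bp and 701 ± 266 bp against 3332 ± 139.6 bp. SIN3A and NCOR1 had H3K9ac lengths of 908 ± 258 bp against 2879 ± 151 bp and 1157 ± 303 bp against 3197 ± 281 bp. Of acetyltransferase and bromodomain genes, 12 of 18 H3K27ac windows fell and 1 rose (15 and 1 adjusted over the list alone), and 14 of 18 fell for H3K9ac. KAT2B went from 1255 ± 134 bp of H3K27ac to none, and KAT6A from 1157 ± 122 bp of H3K9ac to none. KAT6B and ACSS2 had H3K27ac lengths of 529 ± 67.1 bp against 1612 ± 47.1 bp and 401 ± 394 bp against 3163 ± 571 bp, and EP300 and BRD1 H3K9ac lengths of 653 ± 419 bp against 2659 ± 267 bp and 1635 ± 46 bp against 3067 ± 371 bp. BRD3 had 929.7 ± 374 bp against 2761 ± 86.2 bp and 937 ± 32.7 bp against 2478 ± 149.7 bp, while over its whole span both lengths were higher with butyrate. The gene that rose was KAT5, named after its value was seen. In a window at its 3′ end that also holds an end of RNASEH2C, KAT5 had 2309.7 ± 247 bp against 1541 ± 359.7 bp. Its direction turned with a stricter score, and its call was lost in 6 of 18 alternatives. Neither list passed camera (adjusted p = 0.62 and 0.34 for deacetylases, 0.78 and 0.53 for acetyltransferases).

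**Figure D2:**
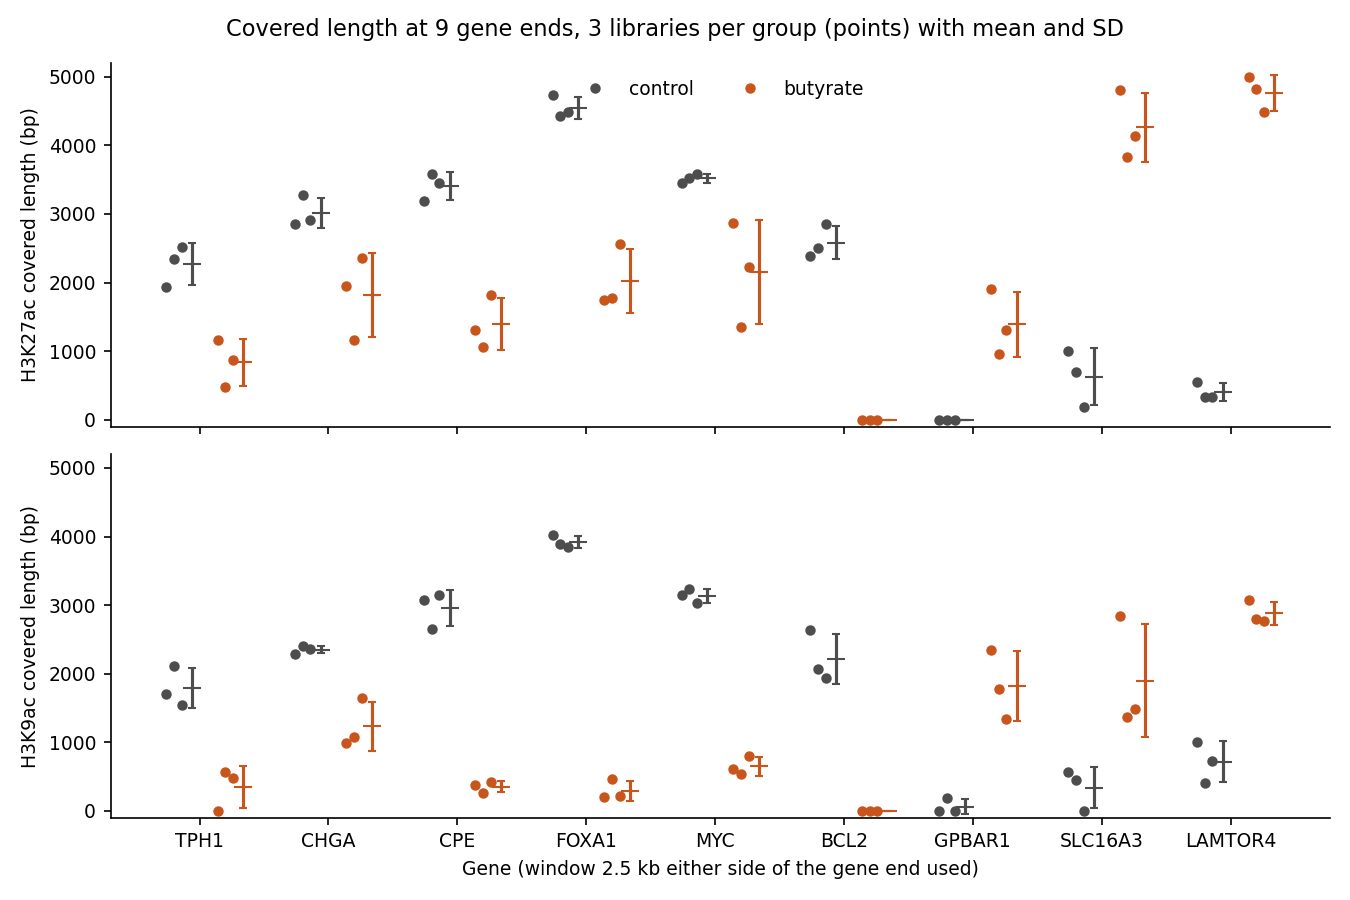
Covered length (bp) of H3K27ac (top) and H3K9ac (bottom) in the window around the gene end used for 9 genes; points are the 3 libraries of each group, horizontal bars the mean and whiskers the SD. TPH1, CHGA, CPE, FOXA1, MYC and BCL2 lie lower with butyrate for both marks. GPBAR1, SLC16A3 and LAMTOR4 lie higher, in windows at their 3′ ends that also hold an end of another gene.

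Apoptosis genes fell in 12 of 17 H3K27ac windows and 11 of 18 H3K9ac windows (12 and 12 adjusted over the list alone). BCL2, an inhibitor of apoptosis, had 2583 ± 243 bp of H3K27ac and 2217 ± 366 bp of H3K9ac in control and none with butyrate. CASP9 had an H3K27ac length of 1116 ± 345 bp against 3391 ± 34.3 bp, and XIAP and BCL2L11 H3K9ac lengths of 252 ± 272 bp against 3038 ± 120.2 bp and 658 ± 148 bp against 2933 ± 190.1 bp. PMAIP1 had 543 ± 89 bp against 2839 ± 282 bp and 374 ± 224 bp against 2286 ± 168 bp. BCL2L1 and BAX rose for H3K27ac at their 3′ ends and were named after their values were seen. They had 4328 ± 211 bp against 3515 ± 302 bp and 2292 ± 869 bp against 927 ± 33.9 bp. Mucosal barrier and cytokine genes fell in 7 of 12 H3K27ac and 9 of 11 H3K9ac windows in both counts. NFKB1 had 1522 ± 391 bp against 3521 ± 142 bp and 254 ± 221 bp against 3143 ± 103 bp, OCLN 922 ± 301 bp against 2356 ± 167 bp and 524 ± 198 bp against 2291 ± 92.1 bp, and TFF1 1019 ± 306 bp against 3030 ± 289.6 bp of H3K9ac. MUC1 had 1293 ± 414 bp against 2473 ± 215 bp of H3K27ac, a call lost under scaling. CLDN3 had 2769 ± 438 bp against 3981 ± 172 bp of H3K27ac and CLDN4 3683 ± 139 bp against 4934 ± 58.3 bp of H3K9ac. Both differences turned under scaling, but control peaks nearly filled the CLDN4 window and scaled lengths were not capped. CLDN7 and RELA rose for H3K27ac at their 3′ ends, named after their values were seen. They had 4712 ± 208 bp against 3768 ± 545 bp and 4807 ± 190.2 bp against 4026 ± 343 bp. The CLDN7 window also holds an end of ELP5. Calls of BCL2L1, BAX, CLDN7 and RELA were lost with lane as a term, and the directions of BAX and CLDN7 turned with a stricter score. Neither list passed camera (adjusted p = 0.78 and 0.69 for apoptosis, 0.78 and 0.34 for the barrier list).

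Ion channels of excitability and mechanosensing fell in 8 of 14 H3K27ac and 8 of 16 H3K9ac windows in both counts. CACNA1D, a calcium channel gene, had 789 ± 883 bp against 3623 ± 243 bp and 182 ± 315 bp against 2890 ± 383 bp, and the sodium channel gene SCN2A 457 ± 154 bp against 1524 ± 85.3 bp and 100.3 ± 174 bp against 1497 ± 67.7 bp. PIEZO1, a mechanosensitive channel, had 32.7 ± 56.6 bp against 981 ± 65.6 bp of H3K27ac, which turned over the whole gene span, and SCN8A 167 ± 145 bp against 1096 ± 222 bp. CACNA2D1 and SCN3A had H3K9ac lengths of 1011 ± 440.4 bp against 4231 ± 307 bp and 187 ± 324 bp against 1763 ± 104 bp. TRPM5, named after its value was seen, rose for H3K27ac at its 3′ end, in a window that also holds an end of TSSC4. It had 1537 ± 143 bp against 1177 ± 149 bp, a call lost in 13 of 18 alternatives and turned in 2. Neurotransmitter receptors fell in 4 of 5 H3K27ac and 4 of 8 H3K9ac windows (4 and 2 adjusted over the list alone). CHRNB4, CHRM3 and ADRB1 lost all covered bases of both marks, from H3K27ac lengths of 725 ± 76.4, 665 ± 111 and 584 ± 47.5 bp. Their H3K9ac lengths in control were 359 ± 120, 528 ± 336 and 848 ± 231 bp, and the H3K9ac calls of CHRNB4 and CHRM3 were lost in 9 and 8 of 16 alternatives. ADRA2A had no covered base in any library. Neuronal genes fell in 7 of 12 H3K27ac and 5 of 13 H3K9ac windows (7 and 4 adjusted over the list alone). MAP2 had 446 ± 296 bp against 2407 ± 200 bp and 475 ± 446 bp against 2221 ± 305 bp, and GAP43 1437 ± 243 bp against 2764 ± 142 bp and 357 ± 346 bp against 2582 ± 75.9 bp. SYN1 and SLC17A7 had H3K27ac lengths of 0 ± 0 bp against 926 ± 45 bp and 273 ± 261 bp against 1465 ± 183 bp, and DCX an H3K9ac length of 444 ± 499.6 bp against 1672 ± 147 bp. ELAVL3, named after its value was seen, rose for H3K27ac at its 3′ end, next to PRKCSH. It had 515 ± 244 bp against 0 ± 0 bp, a call lost in 5 of 14 alternatives. None of the 3 lists passed camera (adjusted p from 0.78 to 1.0 for H3K27ac and from 0.28 to 0.93 for H3K9ac).

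Cytosolic ribosomal protein genes fell in 25 of 53 H3K27ac and 34 of 53 H3K9ac windows (23 and 34 adjusted over the list alone), with camera adjusted p = 0.78 and 0.69. RPS29 had 839 ± 351 bp against 2911 ± 57 bp and 180.3 ± 166 bp against 2767 ± 73.2 bp. RPL15, RPS20 and RPL30 had H3K27ac lengths of 917 ± 39.2 bp against 1973 ± 27.6 bp, 70.3 ± 122 bp against 1373 ± 99.6 bp and 1336 ± 164 bp against 2449 ± 100.2 bp, and RPL7, RPL4 and RPS23 H3K9ac lengths of 799.7 ± 207 bp against 3203 ± 57.6 bp, 894 ± 99 bp against 3395 ± 396 bp and 632 ± 12.4 bp against 2078 ± 152 bp. Markers of other cell types were mostly not covered. Tested H3K27ac windows numbered 6 of 22 for exocrine pancreas, 2 of 20 for fibroblasts, 8 of 20 for blood cells, 5 of 22 for liver and 1 of 20 for germline. Of these, 1, 1, 3, 3 and 1 fell in this order. Only the exocrine list had a rise, at the 3′ end of CFTR (373 ± 139.8 bp against 0 ± 0 bp, a call lost in 7 of 15 alternatives). COL1A1 (70 ± 121 bp against 447 ± 137 bp, lost in 9 of 17 alternatives), CD79A (0 ± 0 bp against 837 ± 86.2 bp), LCP1 (82 ± 142 bp against 1529.7 ± 416 bp) and ASGR1 (411 ± 508 bp against 1241 ± 120.4 bp, lost in 7 of 18 alternatives) fell for H3K27ac. For H3K9ac 0 of 4, 0 of 5, 2 of 8, 2 of 5 and 2 of 2 tested windows fell and none rose, with SPI1 at 0 ± 0 bp against 534 ± 65.7 bp and MAEL at 154 ± 267 bp against 1111 ± 302 bp. CD8A had 128 ± 113 bp against 579.7 ± 90.9 bp and 145 ± 251 bp against 884 ± 209.8 bp, and the liver genes TF and TAT had 903 ± 225 bp against 2519.7 ± 225 bp and 1877 ± 47.6 bp against 2692 ± 98.1 bp of H3K27ac, the latter turning under scaling. Their H3K9ac lengths were 571 ± 315 bp against 1730.3 ± 205 bp and 336 ± 291 bp against 1887 ± 12.5 bp. TDRD1 had 730.3 ± 191 bp against 2135 ± 284 bp and 863 ± 296 bp against 2069 ± 160.1 bp. The windows of CD79A, SPI1, MAEL, TF and TDRD1 also hold ends of ARHGEF1, MYBPC3, ILDR2, TOPBP1 and CCDC186, in this order. Coverage there cannot be assigned to the marker genes alone. Adjusted over the lists alone, the counts of lower and higher windows in these 5 marker lists were unchanged for both marks. By camera with the preset correlation none of these marker lists passed (adjusted p from 0.068 to 0.97 for H3K27ac and from 0.093 to 0.69 for H3K9ac), and the fibroblast (H3K27ac) and germline lists had too few windows for it. With equal peak numbers the exocrine list stood above other windows for H3K27ac (adjusted p = 0.046). At unchanged peak numbers this list had an adjusted p = 0.98 in camera with an estimated correlation. Its median H3K27ac control length was 824 bp, against 1620 bp over all windows. Scaling ended the H3K27ac calls of SYT4 and GAP43 and the H3K9ac calls of BRD1, KLF6, RHOB, DCX, CD8A, TF, TDRD1 and MAEL. Camera pointed up while the median difference was negative for the channel, barrier, ribosomal, metabolite and blood cell lists (H3K27ac) and for all marker, receptor and neuronal lists tested (H3K9ac). In all, 0 of 19 lists passed camera for H3K27ac (3 at an unadjusted p under 0.05) and 2 of 20 for H3K9ac.

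The marks differed in how they responded at part of the gene ends. In the test of the difference, 1839 of 22559 windows passed (limma interaction). The butyrate effect on H3K27ac exceeded that on H3K9ac at 1343, and the reverse held at 496. Both marks had lower means with butyrate at many of these, with H3K9ac the more reduced at 573 and H3K27ac at 295. HABP2 had effects of 4070 bp for H3K27ac and 273 bp for H3K9ac (adjusted p of the difference = 1.5e-05), and CCDC17 gained H3K27ac with no covered H3K9ac base in any library. MACC1 lost much H3K9ac, while its H3K27ac effect was -642 bp (adjusted p of the difference = 7.5e-05). HES1, IRF2BP2 and PTCHD4 had H3K27ac effects of -2014, -2258 and -1080 bp against H3K9ac effects of -4641, -4586 and -4360 bp. CALCA had an H3K27ac effect of -729 bp against -3467 bp. MYT1L and TMSB4X went the other way, with H3K9ac effects of -1043 and -2567 bp against H3K27ac effects of -4493 and -4348 bp. ESPN and KCNN3 gained H3K9ac with no covered H3K27ac base in any library. The direction of the majority depended on list length. With equal peak numbers over the 12 lists, 1030 windows favoured H3K27ac and 1563 favoured H3K9ac. Leaving out 1 library gave 583 to 2022 windows favouring H3K27ac and 177 to 749 favouring H3K9ac.

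New H3K27ac sites lay mainly inside genes, and lost sites lay at gene ends little more often than sites called in all 6 libraries. Over the 6 H3K27ac lists 111143 merged regions were formed. Of these, 8236 were called in all 3 butyrate and no control libraries, 5874 in all control and no butyrate libraries, and 16430 in all 6 libraries. Of the sites called only with butyrate 83.9% lay in gene bodies and 7.77% at gene ends, while 52.7% of the sites called only in control lay at gene ends. For H3K9ac 1145 of 91673 regions were called only with butyrate and 8082 only in control. In gene bodies lay 83.4% of the former, and at gene ends 55.5% of the latter. Of sites called in all 6 libraries, 47.9% lay at gene ends for H3K27ac and 79.9% for H3K9ac. Of H3K27ac sites called in all control libraries, no butyrate library held 20.0% at gene ends, 16.4% in gene bodies and 19.9% between genes. For H3K9ac these shares were 25.9%, 40.0% and 53.0%, so H3K9ac sites at gene ends were lost least often. These shares were not matched for control score. Within deciles of control score, H3K9ac sites away from gene ends were kept in all butyrate libraries more often in 5 of 10. Among sites called in all 6 libraries, the median H3K27ac site kept 63.0% of its control length at gene ends, 91.1% in gene bodies and 88.5% between genes. The H3K9ac medians were 64.3%, 73.6% and 68.7%. The number of sites called only with butyrate depended on the list. With equal numbers of peaks it was 3614 for H3K27ac and 1095 for H3K9ac, and without butyrate replicate 2 it was 16621 and 5682. A stricter score left 233 and 260. More H3K27ac sites were called only with butyrate than only in control, but the balance turned with equal peak numbers (3614 against 9483), with an overlap of 50% of the region (5413 against 11817) and with a stricter score (233 against 13372).

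Long H3K27ac regions, made by stitching peaks within 12 kb and reaching 20 kb, numbered 850 ± 8.50 in control and 1651 ± 411 with butyrate (exact permutation test, p = 0.1). For H3K9ac they numbered 639 ± 128 and 1007 ± 464, with overlapping groups (exact permutation test, p = 0.4). With equal peak numbers the H3K27ac counts were 835 ± 27.8 in control and 1057 ± 74.4 with butyrate, and the H3K9ac counts 292 ± 18.5 and 599.7 ± 122 with no overlap (exact permutation tests, p = 0.1 each). Without butyrate replicate 2 the H3K9ac count was 1273 with butyrate, above all controls (exact permutation test, p = 0.1). Stitching within 5000 bp gave 194 ± 15.0 and 744 ± 209 H3K27ac regions (exact permutation test, p = 0.1), and 96.3 ± 53.3 and 305 ± 215 H3K9ac regions with overlapping groups (exact permutation test, p = 0.3). All 3 butyrate and no control H3K27ac libraries had such a region at 435 places, and the reverse held at 39. The H3K9ac counts were 64 and 52. Among the longest of the 435 was a region over UHRF1, ARRDC5 and the demethylase gene KDM4B (chromosome 19, 4910673 to 5153490), where peaks covered 73.6 ± 15.6 kb with butyrate and 7.42 ± 0.57 kb in control. Another lay over CARM1, a histone methyltransferase, and SMARCA4, the BRG1 chromatin remodeller, with YIPF2, TIMM29 and C19orf38 (chromosome 19, 10864790 to 11067361). It had 77.6 ± 9.91 kb and 17.7 ± 0.098 kb. Further regions lay over GNB1, NADK, CDK11A, CALML6 and TMEM52 (chromosome 1, 1720119 to 1918959, 84.2 ± 8.62 kb and 26.3 ± 0.48 kb), and over NSD2, LETM1 and NELFA (chromosome 4, 1824469 to 2011034, 32.9 ± 8.65 kb and 12.5 ± 0.81 kb). Among the 5 longest H3K27ac regions of control only, those with gene ends inside were 38.4 kb long at NBEA and 34.0 kb long at GPN2, GPATCH3, NUDC and NR0B2.

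For H3K9ac, long regions called with butyrate only lay within GSE1 (chromosome 16, 85197632 to 85317605, 9.44 ± 5.51 kb and 1.52 ± 0.36 kb covered with butyrate and in control) and within MAD1L1 (chromosome 7, 1842289 to 1954961, 9.28 ± 6.59 kb and 0.79 ± 0.40 kb). Others held CASKIN2, TSEN54 and LLGL2 on chromosome 17, KLHL26 and CRTC1 on chromosome 19, and ZFPM1 on chromosome 16. Regions of control only held VPS13C and C2CD4A (chromosome 15, 62059298 to 62125757, 1.16 ± 0.95 kb with butyrate and 9.18 ± 0.83 kb in control), PIK3C2B and MDM4, and DUSP1. The marks also overlapped less with butyrate. Of H3K27ac peaks, 51.3% ± 3.95 overlapped an H3K9ac peak of the same replicate in control and 24.4% ± 2.27 with butyrate. Of H3K9ac peaks, 76.7% ± 3.96 overlapped an H3K27ac peak in control and 53.3% ± 3.54 with butyrate (exact permutation tests, p = 0.1 each, the smallest possible). The overlap depends on the lengths of both lists. With equal peak numbers it was 66.6% ± 2.72 in control and 31.2% ± 2.39 with butyrate for H3K27ac peaks, and 85.6% ± 0.73 and 40.1% ± 2.68 for H3K9ac peaks (exact permutation tests, p = 0.1 each).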

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

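The tests of technical explanations in this part were chosen after the results were seen. The marks responded differently at 1839 gene-end windows, and 51 windows had higher H3K27ac and lower H3K9ac with all 3 tests passed, while 14 had the reverse. Both were picked out because the effects of butyrate on the marks differed in a test of the difference. That test was on base pairs, so where both marks fell, unequal control lengths can also give a difference. Named after their values were seen, the 3 coding genes with the smallest p of the difference among the 51 were BAZ2A, PHYKPL and MEA1. The end used was the 5′ end for BAZ2A and the 3′ end for PHYKPL and MEA1. The BAZ2A window also holds an end of ATP5F1B, so its coverage cannot be assigned to BAZ2A alone. BAZ2A, a repressor of ribosomal RNA genes, had 4186 ± 60.4 bp against 2137 ± 165 bp of H3K27ac and 495 ± 24 bp against 1001 ± 28.2 bp of H3K9ac with butyrate and in control. PHYKPL, whose window lies within HNRNPAB, had 4224 ± 337 bp against 2113 ± 84.5 bp and 1652 ± 78.8 bp against 2465 ± 256 bp, and MEA1, next to PPP2R5D, 2821 ± 209.5 bp against 1262 ± 181 bp and 1597 ± 141 bp against 2903 ± 449 bp. The direction of H3K27ac at PHYKPL (-974 bp) and MEA1 (-719 bp) turned with a stricter score, which also ended that call at BAZ2A. Scaling turned H3K9ac at PHYKPL (247 bp) and ended the H3K9ac calls of BAZ2A and MEA1. The H3K9ac call of BAZ2A was also lost with 5000 bp windows and over the whole gene span, and that of PHYKPL with 1000 bp windows and over the whole gene span.

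The wide loss at gene ends was weighed against weaker peak calling in the butyrate libraries and against the sequencing lane. Scores were lower in every butyrate list, as weaker calling would give. Upper quartiles were 10.4 to 10.5 against 67.3 to 85.0 for H3K27ac, and 7.80 to 8.80 against 32.9 to 41.9 for H3K9ac. Weaker calling was assumed to drop gene-end and distal sites of the same control score about equally often. Distal sites were kept more often in 10 of 10 score deciles for H3K27ac and in 5 of 10 for H3K9ac. A site counted as kept where butyrate peaks lay anywhere in its merged region, and the gene-body share of peaks rose with butyrate. New peaks could thus keep distal sites, so weaker calling remains a possible cause for both marks. With lane as a term, 67.0% of the H3K27ac and 78.7% of the H3K9ac lower calls stayed, but this sets the butyrate libraries against control replicate 1 alone, so the lane remains a possible cause. No scaling by the reference chromatin was used here, so a change in peaks over a changed background could not be told from a change in acetylation itself.

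The H3K27ac sites called only with butyrate could come from the longer butyrate lists. With equal numbers of peaks 3614 such sites were left, so equal list length did not remove them. The other splits of the libraries held at most 158, but each mixes the treatments, so this is no measure of what list length gives. Equal numbers also keep lower-scoring peaks in the butyrate lists, and a stricter score common to all lists left 233. The test therefore does not exclude longer lists.

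Splitting the 6 samples 3 against 3 in every other way gave no window call for either mark or for the difference, against 14358, 13190 and 1839 real ones. For sites called in 1 treatment only the highest other counts were 391 for H3K27ac and 800 for H3K9ac, against 14110 and 9227. For lists they were 1 and 1, against 0 and 2. The real split was the only one as large (1 of 10) for all of these but the H3K27ac lists, where all 10 were as large. With 10 splits a share under 0.05 cannot be reached. Each of the other splits mixes the treatments, so a treatment effect adds to the spread within its groups. Low counts there follow in large part from this and are no measure of false calls.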

How the results depend on the processing

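Of the named-gene results under single alternatives, 3216 kept their call, 207 kept direction but lost it, 7 gained it and 21 turned. Of named genes, 61 of 104 for H3K27ac and 61 of 91 for H3K9ac kept their call under every alternative that gave a value for them (14 to 18 alternatives per gene, fewer where too few libraries were covered). Of the list tests, 111 were the same, 4 weaker and 2 stronger. Windows at transcript starts, listed beforehand, were not run, since the annotation has none. Whole gene span, protein-coding genes only and lane as a term were chosen after seeing the data. The cause was not tested for any change below, except that fewer genes or samples enter where the setting says so. Read depth is unknown, so its limit cannot be given.

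A stricter score gave differences of -18144 (H3K27ac) and -13332 (H3K9ac) in peak number, and for H3K27ac 222.5 bp in median width and 3.17 points in the intergenic share. It left 233 and 260 sites called only with butyrate, 13372 H3K27ac sites called only in control, and 146 and 126 higher windows. It turned the H3K27ac differences of TRPM5 (-952 bp), KAT5 (-1456 bp), BAX (-511 bp), CLDN7 (-389 bp), PHYKPL (-974 bp) and MEA1 (-719 bp). Equal peak numbers gave 3614 H3K27ac sites only with butyrate and 9483 only in control. They gave 1563 windows where the H3K9ac effect was the greater, -136 bp at TRPM5, 1 list past the threshold for H3K27ac and 0 for H3K9ac. With an estimated correlation 0 lists passed for H3K9ac. Scaling gave 3109 higher and 8049 lower windows for H3K27ac, 1835 and 6324 for H3K9ac, and 1368 where the H3K9ac effect was the greater. It turned H3K27ac at CALCA (1181 bp), CLDN3 (118 bp) and TAT (136 bp), and H3K9ac at CLDN4 (1025 bp) and PHYKPL (247 bp). Scaled lengths were not capped at the 5001 bp of a window. At nearly full windows, such as those of CALCA and CLDN4, they can exceed what a window holds.

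Without stitching hardly any region reached 20 kb (means of 1 with butyrate and 1.67 in control for H3K27ac, 0 and 0 for H3K9ac), so the differences of -0.667 and 0 decide nothing. Calling sites in most libraries gave 21055 (H3K27ac) and 7324 (H3K9ac) only with butyrate and 12378 H3K9ac sites only in control. An overlap of 50% of the region gave 5413 and 557 only with butyrate, and 11817 and 12464 only in control. Higher H3K27ac windows numbered 1999 with 5000 bp windows, 669 when covered in 4 libraries, 2433 over the whole gene span, 407 among coding genes and 659 with lane as a term. For H3K9ac they numbered 144 among coding genes and 60 with lane as a term. Over the whole span H3K27ac turned at CALCA (431 bp), PIEZO1 (3977 bp), SIRT3 (170 bp), BRD3 (8342 bp) and PDK4 (679 bp), and H3K9ac at BRD3 (2572 bp). With 1000 bp windows H3K27ac turned at SLC17A7 (17.7 bp) and RELA (-63.3 bp), and with 5000 bp windows at LPAR5 (-41.3 bp).

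Leaving out 1 library at a time moved the difference in H3K27ac covered length from -4.64 to 3.96 Mb, in H3K9ac peak number from -4362 to 8912, and in the H3K9ac intergenic share from -1.78 to 0.0996 points. Sites only with butyrate ranged from 8609 to 16621 for H3K27ac and from 1230 to 5682 for H3K9ac. Higher windows ranged from 897 to 1894 and from 131 to 726. Windows with the greater H3K27ac effect ranged from 583 to 2022, and those with the greater H3K9ac effect from 177 to 749.

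With the replicate number as a block, 1175 H3K27ac windows were higher and 12552 lower, and 273 and 11971 for H3K9ac. Windows with the greater H3K27ac effect were 1612 and those with the greater H3K9ac effect 579. The block gave 0 lists for H3K27ac and 3 for H3K9ac, the granule list being added (adjusted p = 0.0352 in camera, and without the block adjusted p = 0.898 with an estimated correlation). With group means subtracted, same-numbered libraries of the treatments had correlations from -0.0498 to 0.101. Not every library correlated best with its own number, so the numbers do not pair them. Differences per library were unchanged by the replicate block, for instance 33835 peaks for H3K27ac and 252 for H3K9ac (exact sign-flip permutation, p = 0.25 and 1).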

Other observations

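The test in this part was written before its result was seen, but after the nearness of new sites to control regions and the counts of new sites per gene were known. Among the genes with the most H3K27ac sites called only with butyrate were ANKRD11, a chromatin regulator (53 sites), the remodeller SMARCA4 (42), the demethylase KDM4B (40), PRRC2B (36) and the G protein subunit GNB1 (34). For H3K9ac they were GSE1 (22), KDM4B (9) and MAD1L1 (8). At least 1 such site lay in 2599 coding genes for H3K27ac and in 740 for H3K9ac. Of the H3K27ac sites 60.1% lay within 10 kb of a region called in all control libraries, against 18.2% of random positions (17.2% to 19.3% in 100 draws). For H3K9ac the shares were 66.4% and 16.4% (at most 19.2%). Random positions were drawn evenly along each chromosome and were not matched to gene bodies, where most new sites lay. Part of the excess can come from that. Among the 1000 highest-scoring H3K27ac peaks of each library, 77.0% to 80.6% lay at gene ends in control and 36.3% to 44.2% with butyrate. For H3K9ac these shares were 87.7% to 88.8% and 73.7% to 82.9%.

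A hypothesis was that new H3K27ac sites arise in genes whose ends are already acetylated in control cells, beyond what gene length gives. Coding genes with an end window covered in all 3 control libraries held such a site in 19.2% of cases (2274 of 11832), and coding genes with no covered base there in 3.50% (265 of 7568). Within groups of like gene span, the acetylated genes held one more often in 10 of 10 deciles. This nearly follows from the nearness of new sites to control regions and their place in gene bodies, both known before, so the hypothesis stays open.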
